A study of Homo sapiens with 12 samples.

How the data were processed

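HEK293T cells, a transformed human embryonic kidney line, were profiled by CUT&Tag, in which an antibody guides a protein A-Tn5 transposase to the chromatin it binds and the tagged DNA is sequenced. Pan-specific antibodies to lysine pyruvylation (Kpy), lysine lactylation (Kla) and lysine acetylation (Kac) were each used on cells given PBS or 20 mM oxamate, an inhibitor of lactate dehydrogenase, for 24 h. Each library came from 100000 cells and 1 µg of antibody. There were 12 libraries in 6 groups of 2. The labels do not say whether the 2 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries.

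The deposited table holds raw counts per window, with no normalization, for all 12 libraries. The windows are 3999 bp wide and centred on transcription start sites, with coordinates on hg38. Per the labels, FastQC 0.11.9, Bowtie2 2.4.4 and ChIPseeker 1.34.1 were used upstream; the counter, the read filters and the handling of duplicate reads are not given in the sources used here. No control library without a specific antibody was used here, so values are levels relative to each library's window total and not enrichment over background. A list of genes of other cell types was meant to serve as background measured in the same way. Its mean ran from 34.5 to 48.1 CPM per library, near the median window (36.3 to 39.9 CPM) and above olfactory receptor windows (5 to 22.3 CPM), so it stands for average windows and not for background. Of 24182 table entries, 20 repeated the coordinates of an earlier entry and 330 others repeated the counts of an earlier entry in every library. The remaining 23832 windows were kept. Of all entries, 190 had no count in any library. Such entries have identical counts, so the 330 include distinct empty windows. Gene symbols were taken from the Entrez IDs in the table through RefSeq. In all, 24070 entries matched and 1819 of them took a symbol other than the printed one, so some windows sit at the start of a neighbouring transcript. No column of values was left out.

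Counts were normalised by trimmed mean of M-values (TMM) and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit, glmQLFTest). A single fit had 1 coefficient per group over all 12 libraries, which left 6 residual degrees of freedom and a median of 27.1 prior degrees of freedom. After filterByExpr, 23352 windows of 19995 genes were tested. P-values were adjusted by the Benjamini-Hochberg method over all windows within a comparison, with a threshold of 0.05. The 9 comparisons were oxamate against PBS in each of the 3 marks, the 3 pairwise differences of those oxamate effects (interaction contrasts), and the 3 pairwise comparisons of marks in PBS. The antibodies differ, so the last 3 compare how signal was distributed over windows and not amounts of modification. The oxamate comparisons are also relative, since each library was scaled to its own windows. A rise or fall of a mark by the same factor at all windows would not appear in them. All log2 fold changes are given with the standard error (SE) of the fit, and levels in CPM (counts scaled to a common normalised window total) with the SD between 2 libraries.

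Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 on log2 CPM (prior count 2), with 1 window per gene symbol, the one with the highest mean count. The correlation estimated from the data and fry were alternatives; fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. P-values of lists were adjusted over the lists within a comparison. List medians are of edgeR log2 fold changes. Those with a library left out, a term added or a trend removed are of log2 CPM, as are the list values given as before a term or trend. The 2 kinds differ slightly for the same list. The 22 lists were glycolysis and lactate export; pyruvate entry and tricarboxylic acid cycle; the nuclear-encoded respiratory chain; lysine acyltransferases; lysine deacylases; hypoxia-inducible factor targets; amino acid and integrated stress response; unfolded protein response and heat shock; p53 targets; E2F targets and DNA replication; cytosolic ribosomal proteins; ribosome biogenesis; cholesterol biosynthesis and uptake; NRF2 targets and pentose phosphate pathway; immediate early genes; replication-dependent histones; HOX clusters; developmental transcription factors; interferon-stimulated genes; housekeeping promoters; genes of other cell types; and proximal tubule, nephron and neuronal markers. They hold 767 entries for 756 distinct genes, of which 545 had a tested window. The lists, comparisons, tests and the rule for naming genes were fixed before the data were examined.

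By that rule, named windows were past the threshold, had a gene symbol other than a LOC, MIR, RNU, SNOR or clone name and a mean of at least 20 counts, and had both libraries of 1 group above both of the other. The 8 largest rises and 8 largest falls were taken for oxamate and the 5 largest in each direction for the other comparisons. Where fewer than 3 windows passed, the 5 with the lowest p are named as not passed. HAT1, EP300, SIRT3, LDHA and LDHB were always to be named, and 2 to 4 members with the lowest p were to stand as examples of a list, of which the text gives fewer or leaves some out for several lists.

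Folds against windows with 1 to 3 counts are given with an exact 95% interval of the count ratio, and against a group with no counts as a lower bound computed from 3 counts over the group. Duplicate reads cannot be recognised in a count table, so intervals and such bounds cover counting error only.

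The alternatives fixed beforehand were median-of-ratios factors, window totals alone, no filter beyond 1 count in total, a mean of at least 50 counts, DESeq2 1.42.0, limma voom, a fit of only the groups compared, a replicate block, each library left out in turn, and 1 window per set of overlapping windows. Alternatives chosen after the data were seen were voom and camera with library quality weights, scaling to the list of other cell types, leaving out both Kpy libraries numbered 1, list members also matched by position within 500 bp of a gene end, list tests on only the groups compared, a single Kac PBS library for each comparison against Kac, and the ratio of housekeeping to olfactory receptor windows as a term. The pipeline was tested on simulated data built from the mean level of each window over all libraries and the dispersion of each mark, with 100 windows changed by 2-fold and 100 by 4-fold. At 2-fold it recovered 20% of changed windows in Kpy, 18% in Kla and 13% in Kac, and at 4-fold 68%, 81% and 75%, with 53 false calls in Kpy, 0 in Kla and 1 in Kac.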

Results

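CUT&Tag libraries for Kpy, Kla and Kac were compared in HEK293T cells given PBS or 20 mM oxamate for 24 h, with 2 libraries in each of the 6 groups. The series asks how glycolysis, whose end product pyruvate is the source of the pyruvyl group, is linked to gene regulation through histone pyruvylation. Oxamate blocks the enzyme that interconverts pyruvate and lactate. The count in windows at transcription start sites ranged from 756070 to 1266526 per library for Kpy, from 1540016 to 3045425 for Kla and from 1722222 to 2202511 for Kac. The Pearson correlation of log2 CPM between the 2 libraries of a group, across windows that are not independent replicates, was 0.715 (PBS) and 0.71 (oxamate) for Kpy, 0.916 and 0.883 for Kla, and 0.927 and 0.907 for Kac. The ratio of housekeeping promoters to genes of other cell types, which lie near the median window, was 0.985 and 1.62 in the Kpy PBS libraries and 0.708 and 1.23 in the Kpy oxamate libraries. It ranged from 1.23 to 1.55 in Kla and from 1.62 to 2.11 in Kac. Windows holding nuclear copies of mitochondrial DNA took 2240 ± 1000 CPM in Kpy, 249 ± 26.5 in Kla and 75.6 ± 13.2 in Kac (SD, n = 4). Kpy oxamate replicate 1 had 820 CPM and the other Kpy libraries 2260 to 3070.

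**Figure D1:**
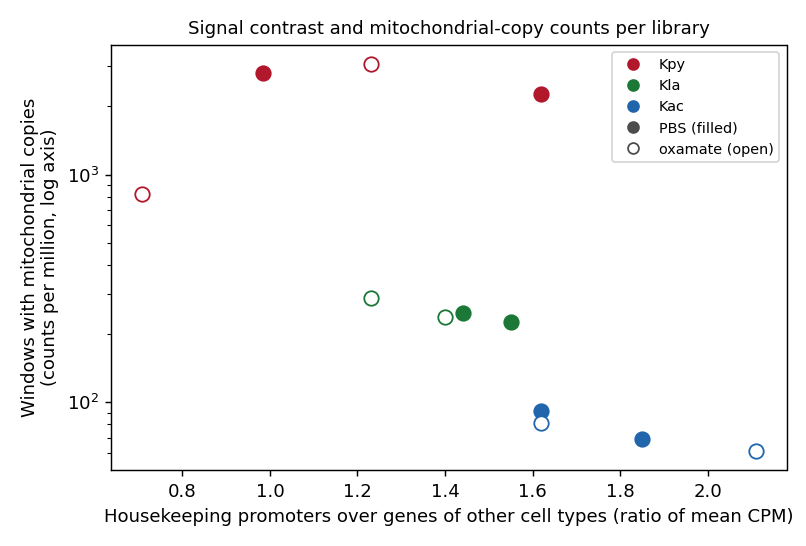
Each point is 1 of the 12 libraries, with the ratio of housekeeping CPM to that of genes of other cell types on the horizontal axis and the CPM of windows holding mitochondrial copies on the vertical log axis, coloured by mark, filled for PBS and open for oxamate. The 4 Kpy libraries lie between 820 and 3070 CPM on the vertical axis and spread from 0.708 to 1.62 on the horizontal axis, while the Kac libraries lie between 1.62 and 2.11.

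In PBS, levels of the 3 marks correlated across promoters. Group means of log2 CPM correlated at 0.889 between Kpy and Kla (Spearman 0.89), 0.891 between Kla and Kac (Spearman 0.864) and 0.787 between Kpy and Kac (Spearman 0.768). Over tested windows, Kpy PBS replicate 2 correlated at 0.84 and 0.853 with the Kla PBS libraries and at 0.773 and 0.779 with Kac PBS. It correlated at 0.715 with Kpy PBS replicate 1, which had 0.57 and 0.579 with Kac PBS. The lower value between Kpy and Kac can therefore not be assigned to the mark rather than to 1 library. Windows are not independent replicates, and with no control library the correlations include any signal common to all libraries. The comparisons of marks ask where the distribution of 1 modification over promoters departs from that of another.

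Kpy and Kac in PBS differed at many promoters. HOX genes, which encode the transcription factors that pattern the body axis, took a smaller share of Kpy than of Kac counts. Their mean level was 49.4 ± 8.06 CPM in Kpy and 140 ± 0.604 CPM in Kac (SD, n = 2). Of 24 measured members 20 were lower, 0 higher and 4 did not pass. In each cluster windows were lower, 4 of 4 in HOXA, 8 of 8 in HOXB (median log2 fold change -1.45), 4 of 5 in HOXC (-1.47) and 4 of 7 in HOXD (-1.18). HOXA5 was at -2.59 ± 0.29 (log2, SE), HOXA7 at -2.16 ± 0.32 and HOXD10 at -1.97 ± 0.31. Cytosolic ribosomal protein genes, the building blocks of the ribosome, had 40 ± 7.12 CPM in Kpy and 82.4 ± 10 CPM in Kac. Of these, 25 of 44 were lower, 0 higher and 19 did not pass. RPS15 was at -2.12 ± 0.33, RPL10A at -1.76 ± 0.29 and RPL5 at -1.81 ± 0.31. Among the single promoters lower in Kpy was SALL4, a transcription factor of embryonic and pluripotent cells (chromosome 20, 51800522 to 51804520, hg38). It had 10.7 ± 5.98 CPM in Kpy against 74.9 ± 19.6 in Kac (log2 -2.71 ± 0.44, adjusted p = 7.2e-05).

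The median log2 fold change was -1.43 for HOX clusters (camera, adjusted p = 6.29e-12; adjusted p = 0.31 with an estimated correlation). It was -1.14 for ribosomal proteins (adjusted p = 7.08e-11; adjusted p = 0.37 with an estimated correlation). Adjusted over the list alone, 22 HOX and 31 ribosomal protein windows were lower. In the same comparison 9 more lists were lower. With a trend on the Kac level removed (see Other observations), 3 of the 11 lists passed: HOX clusters, ribosomal proteins and replication-dependent histones. Integrated stress response genes had a median of -0.65 with 5 lower and 18 not passing (7 lower adjusted over the list alone). The list had adjusted p = 0.000296, and adjusted p = 0.37 with an estimated correlation. Its lower members included the stress-induced factor ATF3 at -1.34 ± 0.29 and the serine synthesis enzyme PSPH at -1.49 ± 0.39. Respiratory chain genes had a median of -0.34 with 8 lower and 40 not passing (7 adjusted over the list alone). This list had adjusted p = 0.000708, and adjusted p = 0.37 with an estimated correlation. The complex I subunit NDUFB1 was at -2.21 ± 0.34. Replication-dependent histones had a median of -0.43 with 2 lower, H2AC17 and H2AC13, and 32 not passing (1 adjusted over the list alone). Their adjusted p was 0.00124, and adjusted p = 0.38 with an estimated correlation. E2F targets had a median of -0.58 with 2 lower, the replication factors MCM5 (-1.50 ± 0.29) and FEN1 (-1.23 ± 0.31), and 27 not passing (2 adjusted over the list alone). Their adjusted p was 0.00301, and adjusted p = 0.2 with an estimated correlation. Housekeeping promoters had a median of -0.57 with 5 lower, such as the translation elongation factor EEF1A1 at -1.27 ± 0.34, and 17 not passing (6 adjusted over the list alone). Their adjusted p was 0.0101, and adjusted p = 0.42 with an estimated correlation. Developmental transcription factors went both ways. Among them 11 were lower, such as FOXC1 at -1.91 ± 0.27 and TBX3 at -1.45 ± 0.25, 4 were higher, such as IRX1 at 4.53 ± 0.90, and 26 did not pass. Adjusted over the list alone, 15 were lower and 5 higher. The median was -0.34 (adjusted p = 0.0153, and adjusted p = 0.31 with an estimated correlation). Of the remaining 3 lists, p53 targets had a median of -0.47 and 1 of 17 lower, the death receptor FAS (adjusted p = 0.0194). Hypoxia-inducible factor targets had -0.26 and 5 of 20 lower, such as the mTOR inhibitor DDIT4 and the angiogenic factor VEGFA (adjusted p = 0.0362). Lysine acyltransferases had -0.52 and 2 of 17 lower, NCOA1 and CREBBP (adjusted p = 0.0401). Each of these 3 had adjusted p = 0.37 with an estimated correlation, and adjusted over the list alone the counts were 1, 6 and 0.

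The other 11 lists did not pass in this comparison. Glycolysis and lactate export had a median log2 fold change of -0.25 (adjusted p = 0.0639), and 2 of its 16 members were lower, the regulator PFKFB3 and the glucose transporter SLC2A3. The median (adjusted p) was -0.24 for pyruvate entry and tricarboxylic acid cycle (0.118), 0.05 for lysine deacylases (0.678; mean -0.03), -0.36 for unfolded protein response and heat shock (0.146), and -0.24 for ribosome biogenesis (0.0868). Cholesterol biosynthesis had -0.12 (0.237), against 0.01 with window totals alone, and immediate early genes had -0.36 (0.0868). NRF2 targets had -0.41 (0.0868), with 1 of 21 higher, the sulfiredoxin gene SRXN1 at 1.99 ± 0.41, and 5 lower, such as malic enzyme ME1 at -1.43 ± 0.30. Interferon-stimulated genes had -0.18 (0.681), genes of other cell types 0.17 (0.413, 5 of 44 higher and 2 lower). Nephron and neuronal markers had 0.01 (0.511), with STMN2 and NEFH higher, 2 of 20.

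The promoters named for a larger share of Kpy than of Kac counts have the largest log2 values, which favours windows with few Kac counts. DPP6, an auxiliary subunit of neuronal potassium channels (chromosome 7, 153885098 to 153889096), had 82 counts in Kpy and 2 in Kac, a ratio of 81.3 (95% interval 21.8 to 682). TFAP2D, an AP-2 family transcription factor (chromosome 6, 50711829 to 50715827), had 86 and 3 counts (ratio 56.8, 18.8 to 281). SCN10A, a sodium channel of sensory neurons (chromosome 3, 38792012 to 38796010), had 80 and 3 counts (ratio 52.9, 17.5 to 262). In the Kac oxamate libraries DPP6 had 7.07 ± 8.26 CPM, TFAP2D 2.45 ± 3.47 and SCN10A 9.28 ± 0.987. The ratios hold only for the PBS libraries in which these windows were picked. MARCHF11, a membrane-bound ubiquitin ligase, had 40.7 ± 4.31 CPM in Kpy and 0.98 ± 1.39 in Kac. MTRNR2L1 had the largest log2 value by the naming rule, 6.98 ± 0.42 (adjusted p = 2.1e-13), with 1750 ± 185 against 13.7 ± 2.74 CPM. Its window (chromosome 17, 22521112 to 22525110) holds a nuclear copy of mitochondrial DNA. In the other direction, TACC2, a centrosomal protein (chromosome 10, 121987175 to 121991173), had 2 counts in Kpy and 92 in Kac (ratio 0.0431, 0.00514 to 0.16). After oxamate TACC2 had 11.2 ± 4.44 CPM in Kpy and 13.7 ± 8.91 in Kac. With SALL4, the noncoding genes LINC01235 (log2 -2.79 ± 0.57) and RBMS3-AS1 (-3.24 ± 0.77) and the pseudogene SNX29P2 (-2.68 ± 0.64) completed the 5 largest differences downward. RBMS3-AS1 and SNX29P2 no longer passed without Kpy PBS replicate 2. The median Kac level in PBS was 6.88 CPM in windows higher in Kpy, 94.1 CPM in windows lower in Kpy and 40.5 CPM in all windows. These medians rest on the same Kac libraries as the comparison.

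For Kpy against Kac in PBS, edgeR called 4326 windows (18.5% of 23352), 2191 higher in 1987 genes and 2135 lower in 1718 genes. The share that was higher, 50.6%, became 63.6% with window totals alone, where the median of all windows moved by 0.129. The named directions and those of the 11 lists held under each scaling. Without Kpy PBS replicate 1 the count was 2006 and 6 lists passed. Those that did not were p53 targets (-0.35), hypoxia targets (-0.20), acyltransferases (-0.19), histones (-0.31) and housekeeping promoters (-0.37). The count was 2093 without Kac PBS replicate 1, when p53 targets (-0.42) and acyltransferases (-0.30) did not pass, and 2317 without Kac PBS replicate 2. Developmental transcription factors (-0.29) no longer passed without Kpy PBS replicate 2.

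**Figure D2:**
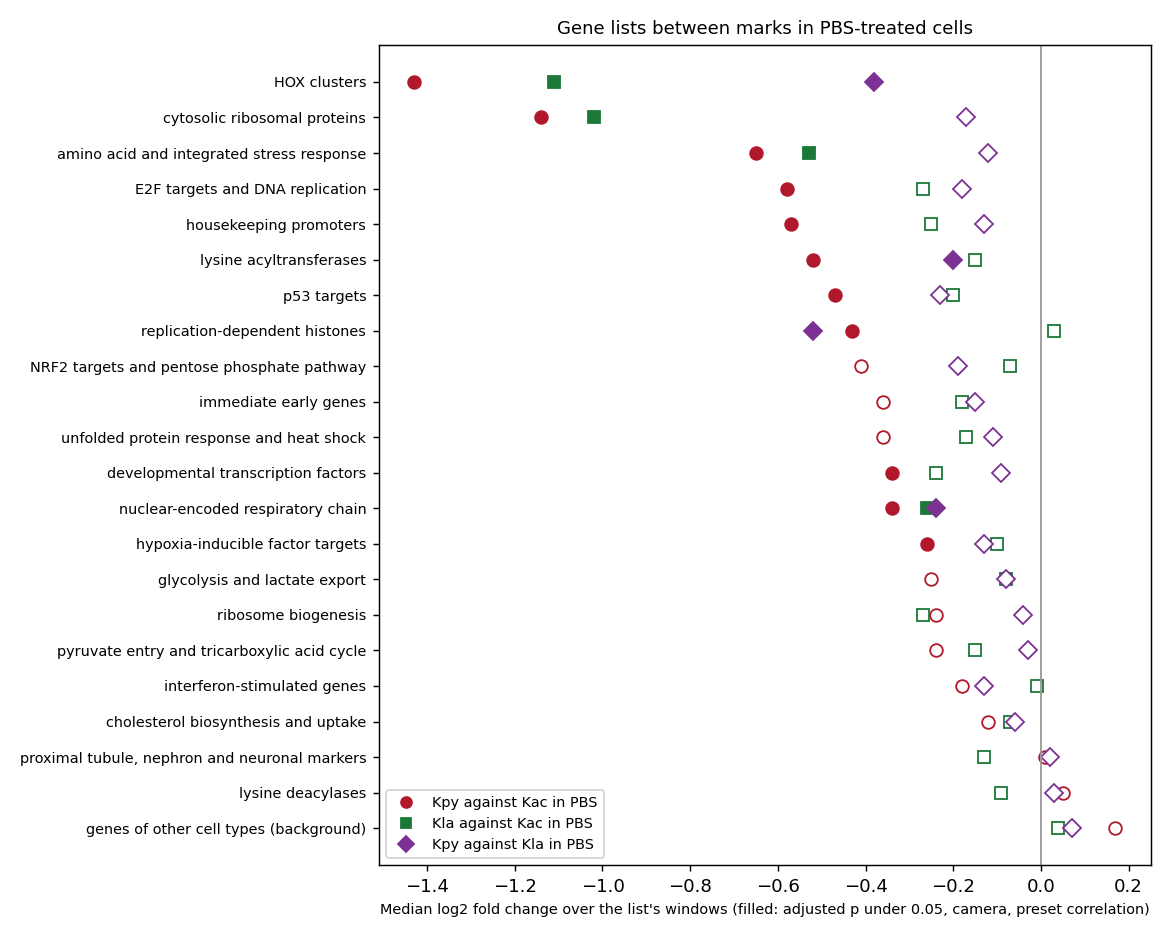
Median log2 fold change of each of the 22 gene lists (vertical axis) in the 3 comparisons of marks in PBS (horizontal axis, log2; colours), with filled points for adjusted p under 0.05 by camera at the preset correlation. HOX clusters lie at -1.43 and ribosomal proteins at -1.14 for Kpy against Kac and at -1.11 and -1.02 for Kla against Kac, and no filled point changes its sign under the other scalings.

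HOX and ribosomal protein promoters took a smaller share of Kla than of Kac counts. With a trend on the Kac level removed (see Other observations), the HOX median on log2 CPM went from -1.12 to -0.25 and no longer passed (camera, adjusted p = 0.165). The ribosomal protein median went from -0.99 to -0.54. Values before removal of the trend follow, with log2 values from the edgeR fit. HOX genes had 64.9 ± 1.08 CPM in Kla and 140 ± 0.604 in Kac (SD, n = 2), with 16 of 24 lower, 0 higher and 8 not passing. HOXA5 was at -1.57 ± 0.25 and HOXC8 at -1.48 ± 0.25. Ribosomal protein genes had 44.1 ± 1.15 CPM in Kla and 82.4 ± 10 in Kac, with 24 of 44 lower, 0 higher and 20 not passing. RPL32 was at -1.64 ± 0.29 and RPL31 at -1.51 ± 0.27. The window of RPS10-NUDT3, which also holds the start of the small-subunit protein gene RPS10 (chromosome 6, 34424050 to 34428048), had 20.6 ± 0.362 CPM in Kla and 99.8 ± 23.9 in Kac (log2 -2.27 ± 0.35, adjusted p = 0.00015). Stress genes ATF3 (-0.98 ± 0.27) and STC2 (-0.91 ± 0.25) and the respiratory subunits NDUFB1 (-1.52 ± 0.31) and ATP5MC2 (-0.95 ± 0.25) were also lower.

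In Kla against Kac in PBS, camera placed 4 lists past the threshold. Ribosomal proteins had a median of -1.02 (adjusted p = 5.82e-11) and HOX clusters -1.11 (adjusted p = 1.4e-10), each with adjusted p = 0.39 with an estimated correlation. Integrated stress response genes had -0.53 (adjusted p = 0.000349, 5 of 23 lower) and the respiratory chain -0.26 (adjusted p = 0.0281, 5 of 48 lower), each with adjusted p = 0.6 with an estimated correlation. Adjusted over the list alone, 29, 19, 5 and 5 windows were lower. The respiratory chain no longer passed without Kac PBS replicate 1 (-0.26), and 7 lists passed without Kac PBS replicate 2. Replication-dependent histones had 32.9 ± 0.483 CPM in Kla and 34.9 ± 2.54 in Kac and did not pass (median 0.03, mean 0.07, adjusted p = 0.988). The other 17 lists had adjusted p from 0.0632 (E2F targets, -0.27) to 0.964 (interferon-stimulated genes, -0.01). Developmental transcription factors had 8 lower and 3 higher (median -0.24, adjusted p = 0.0804).

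Promoters named for a larger share of Kla than of Kac counts were ranked in the same way. Among them ZNF835, a zinc finger gene (chromosome 19, 56669785 to 56673783, adjusted p = 0.00037), had 83 Kla counts and 0 Kac counts, at least 22.4-fold higher. DPP6 had 83 and 2 counts (ratio 33.7, 95% interval 9.03 to 283) and SCN10A 99 and 3 (ratio 26.8, 8.9 to 132). The zinc finger gene ZNF454 had 19.6 ± 3.36 CPM in Kla against 0.98 ± 1.39 in Kac, and the cation channel gene TRPC7 19.4 ± 5.03 against 0.982. In the Kac oxamate libraries ZNF835 had 2.4 ± 0.0738 CPM, DPP6 7.07 ± 8.26, SCN10A 9.28 ± 0.987, ZNF454 2.99 ± 0.756 and TRPC7 7.12 ± 4.87. The ratios and the bound for ZNF835 hold only for the PBS libraries in which these windows were picked. Lower in Kla were the cytokine gene IL26 (-2.75 ± 0.65), ZNF532 (-2.15 ± 0.36), the rod transducin subunit GNGT1 (-2.16 ± 0.54) and the Wnt modulator DKK2 (-2.09 ± 0.59). GNGT1 and DKK2 did not pass when any of the 4 libraries was left out, nor IL26 when any but Kac PBS replicate 1 was.

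EdgeR over all 12 libraries called fewer windows for Kla against Kac than for Kpy against Kac. The order was reversed with limma voom and in a fit of only the groups compared. Across the 23352 windows, edgeR called 2372 for Kla against Kac (10.2%), 1009 higher in 888 genes and 1363 lower in 1099 genes. The share that was higher, 42.5%, became 61.1% with window totals alone, which moved the median of all windows by 0.135, and 66.1% with scaling to the list of other cell types, which moved it by 0.0932 and left 1255 calls. The count was 524 without Kla PBS replicate 1, 560 without Kla PBS replicate 2, 767 without Kac PBS replicate 1 and 819 without Kac PBS replicate 2.

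Kpy and Kla departed from Kac at shared windows: 764 were higher in both, where independent calls would give 94.7, and 1080 were lower in both, where they would give 125. The log2 fold changes against Kac correlated at 0.834 across windows, which are not independent replicates. Both comparisons use the same 2 Kac libraries. With 1 Kac library for Kpy and the other for Kla, an alternative chosen after the data were seen, 112 windows were higher in both (9.84 from independent calls) and 357 lower (27.2), and the correlation was 0.584. With the libraries exchanged the counts were 152 (14.2) and 336 (22.4), and the correlation 0.602. In 20 simulations with no difference between marks, sharing the Kac libraries gave a correlation of 0.444 (at most 0.461). Neither check allows for a flatter distribution over windows in both Kpy and Kla than in Kac, which would also give overlap. The median Kac level was 6.88 CPM in windows higher in Kpy and 9.57 CPM in those higher in Kla. It was 94.1 and 110 CPM in the lower ones. The overlap therefore does not show changes specific to these windows.

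Kpy and Kla differed from each other at few promoters. Replication-dependent histone genes, which supply histones in S phase, had 23.8 ± 8.24 CPM in Kpy and 32.9 ± 0.483 in Kla (SD, n = 2). Of 34 members 31 had log2 values below 0, yet none passed singly. H2BC3 had -2.84 ± 0.89 and H2AC7 -1.15 ± 0.42. HOX genes had 49.4 ± 8.06 CPM in Kpy and 64.9 ± 1.08 in Kla, with 20 of 24 values below 0 and HOXA5 at -1.02 ± 0.29. The olfactory receptor gene OR9I1 (chromosome 11, 58117446 to 58121444) was higher in Kpy, with 50.7 ± 22.9 against 5.15 ± 1.39 CPM (log2 3.23 ± 0.61, adjusted p = 0.018). So was NTM, a neuronal adhesion protein (chromosome 11, 131368479 to 131372477), with 57.1 ± 26.5 against 7.84 ± 0.774 CPM (2.82 ± 0.48, adjusted p = 0.0045). LRRN1, a neuronal leucine-rich repeat protein, had 113 ± 45.1 against 17.8 ± 0.848 CPM (2.65 ± 0.46). The noncoding gene SILC1 had 53.5 ± 2.98 against 9.13 ± 2.6 CPM (2.52 ± 0.49). MTRNR2L1, whose window holds a mitochondrial copy, had 1750 ± 185 against 112 ± 14.1 CPM (3.97 ± 0.34, adjusted p = 7.7e-09).

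In Kpy against Kla in PBS, camera placed 4 lists past the threshold: histones (median -0.52, adjusted p = 4.41e-07), HOX clusters (-0.38, 0.000403), the respiratory chain (-0.24, 0.0392, 30 of 48 values below 0) and lysine acyltransferases (-0.20, 0.0426, 15 of 17 below 0). Each had adjusted p = 0.58 with an estimated correlation, and no member passed over all windows. Adjusted over the list alone, 1 HOX window was lower and none of the other 3 lists had any. None of these 4 passed without Kpy PBS replicate 1 (-0.27, -0.32, -0.21 and 0.00), and only histones and HOX clusters did without Kla PBS replicate 1. The other 18 lists had adjusted p from 0.0567 (ribosomal proteins, -0.17) upward, and lysine deacylases had the highest (median 0.03, against -0.01 with scaling to the list of other cell types).

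For Kpy against Kla, edgeR called 16 windows of 13 genes higher and 0 lower (2094 at unadjusted p under 0.05), and 3 of the 16 hold mitochondrial copies. DESeq2 called 41 and limma voom 94. The count was 4 without Kpy PBS replicate 1, 5 without Kla PBS replicate 1, 3 without Kla PBS replicate 2 and 218 (179 higher, 39 lower) without Kpy PBS replicate 2. OR9I1, NTM, LRRN1 and SILC1 passed in none of the fits without Kpy PBS replicate 1 or a Kla library.

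**Figure D3:**
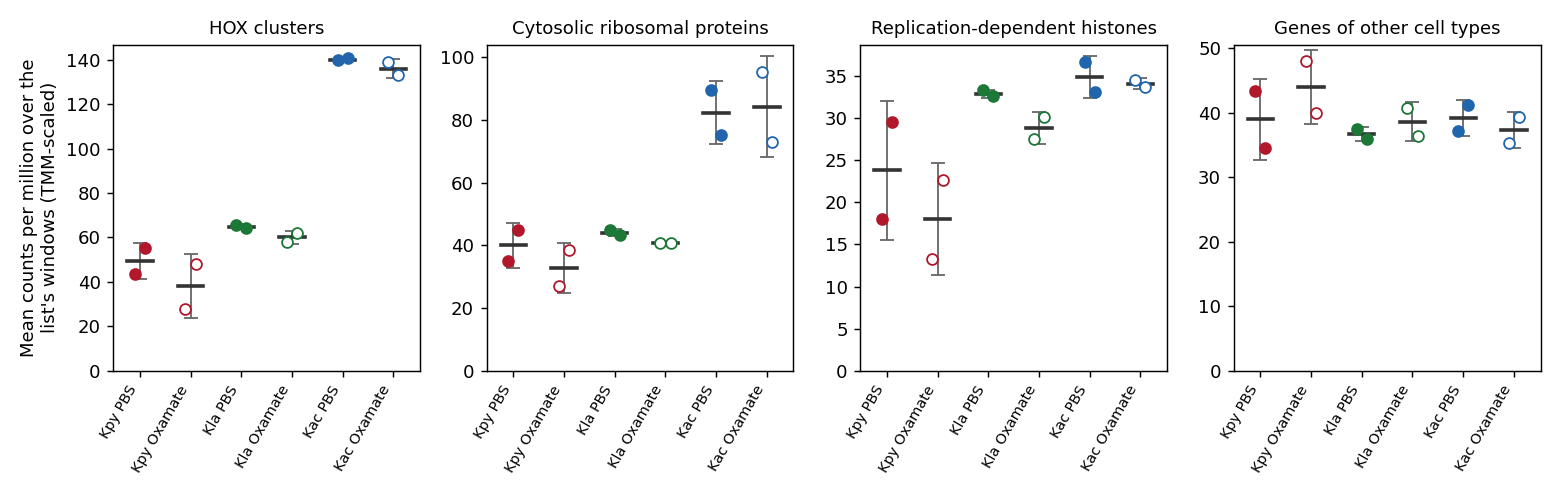
Mean CPM of HOX clusters, ribosomal proteins, replication-dependent histones and genes of other cell types (panels; vertical axis, CPM) in the 6 groups, with a point per library, a bar for the mean and a whisker for the SD (n = 2). HOX promoters have 140 ± 0.604 CPM in Kac PBS, 64.9 ± 1.08 in Kla PBS and 49.4 ± 8.06 in Kpy PBS, and the Kpy oxamate libraries lie at 27.8 and 48.2; the order of the marks in PBS holds under each scaling.

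The main question of the series is what inhibition of lactate dehydrogenase does to promoter pyruvylation. Levels are relative to each library's window total, so a change shared by all promoters would not show, here or in Kla and Kac. After oxamate, HOX promoters had 38 ± 14.4 CPM of Kpy against 49.4 ± 8.06 in PBS (SD, n = 2) and ribosomal protein promoters 32.8 ± 8.05 against 40 ± 7.12. Histone promoters had 18 ± 6.66 CPM against 23.8 ± 8.24, integrated stress response promoters 40.2 ± 10.5 against 49.1 ± 10, and immediate early promoters 57.1 ± 6.03 against 69.6 ± 5.97. Interferon-stimulated promoters had 37.9 ± 2.68 CPM against 30.5 ± 3.73. Housekeeping promoters were also lower, with 41.6 ± 10.7 CPM against 49.4 ± 9.4. Without Kpy oxamate replicate 1 the median log2 fold changes were 0.03 for HOX clusters, 0.01 for ribosomal proteins and -0.09 for histones. They were -0.07 for the integrated stress response, -0.19 for immediate early genes and 0.29 for interferon-stimulated genes. No single promoter passed the test. The lowest adjusted p among nameable windows was at UPF3A, a factor of nonsense-mediated mRNA decay (chromosome 13, 114279585 to 114283583). It had 49.2 ± 11.4 CPM in PBS and 9.35 ± 4.67 after oxamate (log2 -2.37 ± 0.42, adjusted p = 0.076).

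Next was CAND1, an exchange factor of cullin ubiquitin ligases (chromosome 12, 67267282 to 67271280), with 83.9 ± 7.71 CPM in PBS and 29 ± 6.75 after oxamate (-1.53 ± 0.31, adjusted p = 0.2). The ribosome assembly factor WDR74, whose window also holds a U2 RNA gene, had 80.9 ± 5.3 and 25.2 ± 15.7 CPM (-1.66 ± 0.34). The corepressor IRF2BP2 had 142 ± 55.3 and 52.2 ± 38.2 CPM (-1.44 ± 0.31). The lysosomal enzyme AGA had 60.9 ± 17 and 19.5 ± 10.5 CPM (-1.63 ± 0.36). DESeq2 placed UPF3A, CAND1 and WDR74 past the threshold.

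Of the proteins named in the title, HAT1 (chromosome 2, 171920449 to 171924447) had 38.6 ± 27.4 CPM of Kpy in PBS and 34 ± 13.9 after oxamate (-0.24 ± 0.39, adjusted p = 0.9). SIRT3 (chromosome 11, 234933 to 238931, a window that also holds PSMD13) had 28.6 ± 15 and 30.1 ± 2.71 (0.03 ± 0.42, adjusted p = 0.99). Lactate dehydrogenase A, LDHA (chromosome 11, 18392389 to 18396387), had 59.6 ± 18.8 and 47.2 ± 8.35 CPM (-0.36 ± 0.32, adjusted p = 0.78). The window carrying the ID of LDHB lies 98 kb from that gene (chromosome 12, 21755859 to 21759857) and had -0.44 ± 0.66 (adjusted p = 0.89), so it gives no value for the LDHB promoter. EP300 had no window by ID. A window at its start, listed under MIR1281 and chosen after its values were seen (chromosome 22, 41090514 to 41094512), had -0.16 ± 0.30 (adjusted p = 0.91).

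For Kpy: oxamate against PBS, camera placed 7 lists past the threshold, with 0 members up, 0 down and all members not passing over all windows. HOX clusters had a median log2 fold change of -0.42 (20 of 24 values below 0, adjusted p = 0.00149), with HOXB5 at -0.94 ± 0.38. Ribosomal proteins had -0.29 (34 of 44 below 0, adjusted p = 0.00816), with RPL27A at -1.20 ± 0.32 and RPS6 at -1.33 ± 0.38. Histones had -0.42 (23 of 34, 0.00816), with H2AC11 at -1.24 ± 0.37 and H3C1 at -1.12 ± 0.35. Integrated stress response genes had -0.38 (18 of 23, 0.0251), with the stress sensor SESN2 at -0.77 ± 0.28. Housekeeping promoters had -0.33 (18 of 22, 0.0251), with the RNA polymerase II subunit POLR2A at -0.84 ± 0.34. Immediate early genes had -0.37 (12 of 18, 0.0459), with CCN2 at -0.75 ± 0.27 and SRF at -0.76 ± 0.28. Interferon-stimulated genes had 0.29 (4 of 19 below 0, 0.0459), with OAS3 at 1.39 ± 0.55 and IFI6 at 1.06 ± 0.53. All 7 had adjusted p = 0.64 with an estimated correlation. Adjusted over the list alone, 2 ribosomal protein and 2 histone windows were lower, and in lists that did not pass 1 each of ribosome biogenesis and developmental transcription factors. Housekeeping promoters moved with these lists, and the list of other cell types went from 39 ± 6.29 to 44 ± 5.74 CPM (median 0.16, adjusted p = 0.214). Its median was -0.02 with scaling to that list. The other 14 lists had adjusted p from 0.185 (p53 targets, ribosome biogenesis and NRF2 targets) to 0.998 (glycolysis). Glycolysis had a median of 0.06, a mean of 0.00 and a test direction of lower, and -0.16 with scaling to the list of other cell types.

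In Kpy, edgeR called 0 windows after oxamate (2108 at unadjusted p under 0.05), DESeq2 3 lower and limma voom 0. The median SE was 0.382, and 68.9% of windows had log2 values within 0.5 of 0. In simulated data the fit recovered 20% of windows changed 2-fold in Kpy and made 53 false calls, more than the threshold of 0.05 allows. Without Kpy oxamate replicate 2 it called 417 (81 higher, 336 lower) and 8 lists, interferon-stimulated genes (0.24) not among them. Without Kpy PBS replicate 1 it called 2 lower and 9 lists. Without Kpy PBS replicate 2 or without Kpy oxamate replicate 1 it called 0 windows and 0 lists, and the medians of HOX clusters were -0.32 and 0.03.

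Kla after oxamate showed no promoter past the threshold. The 5 windows with the lowest p, none of which passed (adjusted p = 1), began with PDLIM3, a muscle LIM protein (35.1 ± 4.08 CPM in PBS, 11.1 ± 1.31 after oxamate, log2 -1.65 ± 0.43). TANK, a regulator of innate immune signalling, had 23 ± 5.31 and 7.44 ± 3.35 CPM (-1.61 ± 0.47), and SNRNP70 of the U1 splicing particle 59.8 ± 7.18 and 28.2 ± 2.16 (-1.09 ± 0.33). LINC01375 had 4.66 ± 0.703 and 18.6 ± 8.39 CPM (1.97 ± 0.61), and the ribosomal protein gene RPL27A 60.9 ± 1.44 and 31.7 ± 3.68 (-0.94 ± 0.29). HAT1 had 42.3 ± 2.79 and 42.3 ± 3.39 CPM (0.00 ± 0.35) and SIRT3 36.6 ± 2.47 and 40.8 ± 13 (0.15 ± 0.37). LDHA had 51.8 ± 2.51 and 65.7 ± 4.23 (0.34 ± 0.29), the window with the LDHB ID -0.11 ± 0.60 and the EP300 start -0.16 ± 0.28. HOX promoters had 64.9 ± 1.08 and 60 ± 3.02 CPM and ribosomal protein promoters 44.1 ± 1.15 and 40.8 ± 0.0391.

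For Kla: oxamate against PBS, edgeR called 0 windows (409 at unadjusted p under 0.05), as did DESeq2 and limma voom with 0 each. No list passed with camera: the lowest adjusted p was 0.057, for cholesterol biosynthesis (median -0.24) and histones (-0.22), and the lowest with an estimated correlation was 0.57. With the replicate block 2 lists passed. Of the alternatives chosen after the data were seen, library quality weights gave 2 lists and members also matched by position 5. In simulated data 18% of windows changed 2-fold and 81% of windows changed 4-fold were recovered.

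Kac after oxamate also had no promoter past the threshold. Under the naming rule, the 5 windows with the lowest p, none of which passed (adjusted p = 1), began with CCDC38, a coiled-coil protein (71.2 ± 0.91 CPM in PBS, 35.1 ± 1.89 after oxamate, log2 -1.02 ± 0.30). The gut peptide hormone INSL5 had 10.3 ± 2.12 and 28.8 ± 1.73 CPM (1.47 ± 0.44), and the immune receptor kinase SYK 107 ± 25.3 and 54.4 ± 10.2 (-0.97 ± 0.29). The zinc finger gene ZNF250 had 70 ± 5.69 and 38.1 ± 1.6 CPM (-0.88 ± 0.27), and the kinase MAP3K6 84.7 ± 32 and 42.7 ± 11 (-0.98 ± 0.31). HAT1 had 46.7 ± 7.09 and 60.5 ± 1.53 CPM (0.38 ± 0.35) and SIRT3 28.7 ± 1.65 and 23.2 ± 4.53 (-0.31 ± 0.39). LDHA had 86.2 ± 13.8 and 105 ± 35.5 (0.29 ± 0.28), the window with the LDHB ID 0.20 ± 0.56 and the EP300 start 0.03 ± 0.27. HOX promoters had 140 ± 0.604 and 136 ± 4.29 CPM and ribosomal protein promoters 82.4 ± 10 and 84.3 ± 16.

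For Kac: oxamate against PBS, edgeR called 0 windows (584 at unadjusted p under 0.05; lowest adjusted p 0.668), and DESeq2 and limma voom called 0 each. No list passed with camera (lowest adjusted p 0.834, and 0.98 with an estimated correlation), and 1 did without Kac oxamate replicate 2.

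Whether oxamate acted differently on the marks was tested directly as the difference of its effects. Between Kpy and Kac, ribosomal protein promoters had a median difference of -0.33 (33 of 44 values below 0) and HOX promoters one of -0.43 (19 of 24 below 0). RPL27A had -1.16 ± 0.41, RPS6 -1.36 ± 0.49, HOXB8 -1.02 ± 0.42 and HOXD8 -1.20 ± 0.52, and none of the members passed singly. UPF3A, which had 48.9 ± 3.27 CPM of Kac in PBS and 55.5 ± 0.434 after oxamate, differed by -2.56 ± 0.54 (adjusted p = 0.6, not passed). SEZ6L (2.95 ± 0.72), the palmitoyltransferase ZDHHC5 (-1.64 ± 0.41), CAND1 (-1.59 ± 0.40) and the endothelial cadherin CDH5 (1.89 ± 0.49) followed (adjusted p = 0.96 each, not passed).

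In Kpy minus Kac: difference of the oxamate effects, both lists had adjusted p = 0.00944 with camera and adjusted p = 0.86 with an estimated correlation. Adjusted over the list alone, no member passed. The other 20 lists had adjusted p from 0.0814 (housekeeping promoters, -0.40) to 0.999, and interferon-stimulated genes had 0.23 (0.238), against -0.01 with scaling to the list of other cell types. EdgeR called 0 windows (1164 at unadjusted p under 0.05), as did DESeq2 and limma voom with 0 each. It called 10 windows lower without Kpy oxamate replicate 2. Neither list passed without Kpy PBS replicate 2 or without Kpy oxamate replicate 1 (0 lists each), and ribosomal proteins did not pass without Kac PBS replicate 2 (-0.21) or without Kac oxamate replicate 1 (-0.06). The count of lists was 7 without Kpy PBS replicate 1, 6 without Kpy oxamate replicate 2, and 4 without Kac PBS replicate 1 or Kac oxamate replicate 2.

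Between Kpy and Kla, no list and no promoter differed in its response past the threshold, with a median SE of 0.514 over windows. The lowest p (adjusted p = 1, not passed) was at RAB32, a GTPase of lysosome-related organelles (-1.60 ± 0.41), with 98 ± 23.3 and 41.7 ± 9.05 CPM of Kpy and 52.2 ± 9.7 and 69.1 ± 16 of Kla. The ion pump regulator FXYD1 (1.48 ± 0.40) had 40.1 ± 7.59 and 94.5 ± 6.03 CPM of Kpy and 65.9 ± 1.18 and 54.7 ± 0.42 of Kla. ZSCAN18, with 2 counts in each Kpy PBS library, had 3.69 ± 1.01, GIMD1 -2.55 ± 0.73 and synphilin SNCAIP -1.85 ± 0.53. HOX promoters had a median difference of -0.20 (camera, adjusted p = 0.25), histones -0.30 (0.551) and interferon-stimulated genes 0.31 (0.128), the lowest adjusted p of the 22 lists (0.93 with an estimated correlation). The Kpy effects on HOX and histone promoters are therefore not shown to differ from those in Kla. EdgeR, DESeq2 and limma voom called 0 windows (836 at unadjusted p under 0.05 with edgeR). Without Kpy oxamate replicate 2 edgeR called 12 lower and 5 lists passed. Without Kpy PBS replicate 1, 6 lists passed, and 1 did without Kla PBS replicate 2 or Kla oxamate replicate 1. Scaling to the list of other cell types moved the median of all windows by -0.185 in the Kpy oxamate effect and by -0.121, -0.256 and -0.137 in the differences Kpy minus Kla, Kpy minus Kac and Kla minus Kac. The list values are relative to TMM scaling.

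Between Kla and Kac, oxamate effects did not differ past the threshold at any promoter. By the naming rule, the lowest p (adjusted p = 1, not passed) was at SCN10A, with 0 and 3 counts in the Kac PBS libraries (-3.96 ± 1.06). The noncoding gene JRKL-AS1 (-2.73 ± 0.79) had 21.9 ± 2.2 and 10 ± 1.06 CPM of Kla and 3.19 ± 0.338 and 9.91 ± 0.729 of Kac. The matrix protein nephronectin, NPNT (1.43 ± 0.44), had 51.4 ± 10.8 and 71.9 ± 2.22 CPM of Kla and 78.1 ± 7.41 and 40.2 ± 19.5 of Kac. The receptor adaptor GRB7 had 1.30 ± 0.40 and the aminopeptidase AOPEP 1.56 ± 0.49. Ribosomal proteins had a median difference of -0.21 (camera, adjusted p = 0.306) and E2F targets -0.13 (0.306), the lowest of the 22 lists (0.92 with an estimated correlation). EdgeR, DESeq2 and limma voom called 0 windows (396 at unadjusted p under 0.05 with edgeR), and 2 lists passed without Kac PBS replicate 1 or without Kac oxamate replicate 2. Across windows, which are not independent replicates, the oxamate effects correlated at 0.13 between Kpy and Kla, 0.037 between Kpy and Kac and 0.06 between Kla and Kac.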

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

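The test that leaves out 1 library alone (Kpy_Oxamate replicate 1), scaling to the list of other cell types, leaving out both Kpy libraries numbered 1 and the term from olfactory receptor windows were chosen only after the result was seen. The median difference of the log2 oxamate effects between Kpy and Kac was -0.33 at ribosomal protein promoters (33 of 44 below 0) and -0.43 at HOX promoters (19 of 24 below 0). A difference between groups drew attention to these values, by a test of the difference itself. In Kpy minus Kac: difference of the oxamate effects, camera at its preset correlation gave adjusted p = 0.00944 for both lists, and no member passed singly. Over the alternatives adjusted p ranged from 2.14e-05 to 0.989 for ribosomal proteins and from 5.44e-07 to 0.989 for HOX clusters, with 0.86 for both with an estimated correlation and 0.886 with fry. The medians were -0.61 and -0.67 with scaling to the list of other cell types. Neither list passed without Kpy PBS replicate 2, without Kpy oxamate replicate 1 or without both Kpy libraries numbered 1, and ribosomal proteins did not without Kac PBS replicate 2 or Kac oxamate replicate 1.

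The pattern weighed is the lower Kpy signal at HOX, ribosomal protein, replication-dependent histone and integrated stress response promoters after oxamate. To test whether libraries differ in promoter signal over background, the log2 ratio of housekeeping promoters to genes of other cell types was added as a term, and 0 of the 4 lists passed: medians (log2 CPM, SD over members) went from -0.47 ± 0.44 to -0.16 ± 0.45, from -0.29 ± 0.51 to -0.02 ± 0.57, from -0.42 ± 0.68 to 0.01 ± 0.73 and from -0.35 ± 0.36 to -0.01 ± 0.28, so the calls ended because the medians shrank, but those genes lie near the median window, and with olfactory receptor windows in their place, which lie lower, 0 lists passed with medians of -0.37, -0.19, -0.18 and -0.20, so the term does not decide. For 1 library alone (Kpy_Oxamate replicate 1), 0 of the 4 lists passed without it (medians 0.03, 0.01, -0.09 and -0.07), and oxamate replicate 2 lay above PBS replicate 1 in 4 of 4 lists, with HOX clusters at 55.1 and 43.7 CPM in PBS and 48.2 and 27.8 after oxamate. For immediate early promoters (-0.39 ± 0.44 before, -0.24 ± 0.43 after the first term) and interferon-stimulated promoters (0.35 ± 0.47 before, 0.28 ± 0.53 after), 0 of the 2 lists passed with either term, but the medians moved by less than the spread, so a difference in signal cannot be told apart from an effect of oxamate with 2 libraries in each group. Set side by side by replicate number, each of the 4 lists was lower after oxamate in both numbers. Ribosomal proteins went from 34.9 to 27.1 CPM in number 1 and from 45 to 38.5 in number 2. The labels do not say that equal numbers pair libraries. Both technical explanations stay open for the 4 lists, and so does an effect of oxamate on Kpy, which could itself change such ratios and was not tested apart from them.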

How the results depend on the processing

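Library quality weights, scaling to the list of other cell types, leaving out both Kpy libraries numbered 1, list members also matched by position, list tests on only the groups compared and a single Kac PBS library for each comparison were chosen after seeing the data, and the other alternatives before. Among values of named windows over all alternatives, 1010 kept their direction and side of the threshold, 31 fell below it, 12 passed it and 15 reversed; among values of called lists, 202 kept them and 110 fell below it, with 0 reversed. Median-of-ratios factors, window totals alone, no filter and 1 window per set of overlapping windows kept every count within 1.5 times its value, and the oxamate comparisons and differences of effects kept 0 called windows under every setting except those given here. A mean of at least 50 counts, which tests fewer windows, gave 2265 windows for Kpy against Kac in PBS (4326 in the report) and 5 for Kpy against Kla (16), and a fit of only the groups compared, with fewer libraries, gave 2833 for Kpy against Kac and 4561 for Kla against Kac (2372). DESeq2 gave 3 for Kpy: oxamate against PBS (0) and 41 for Kpy against Kla; limma voom gave 94 for Kpy against Kla and 3839 for Kla against Kac, and with library quality weights 118 and 4711. Kpy against Kac had 3795 with voom and 3345 with weights, so under these and the fit of only the groups compared Kla against Kac had the larger count, the reverse of the report. Scaling to the list of other cell types gave 1255 for Kla against Kac, and leaving out both Kpy libraries numbered 1 gave 5 for Kpy against Kla. The cause was not tested for any of these, including the rise for Kla against Kac in the fit with fewer libraries.

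Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave 0 to 417 windows for Kpy: oxamate against PBS, 0 to 0 for Kla, Kac and Kla minus Kac, 0 to 12 for Kpy minus Kla, 0 to 10 for Kpy minus Kac, 2006 to 4525 for Kpy against Kac in PBS, 3 to 218 for Kpy against Kla and 524 to 819 for Kla against Kac. For lists past the threshold the ranges were 0 to 9 for Kpy: oxamate against PBS (7 in the report), 0 to 0 for Kla (0), 0 to 1 for Kac (0), 0 to 6 for Kpy minus Kla (0), 0 to 7 for Kpy minus Kac (2), 0 to 2 for Kla minus Kac (0), 6 to 14 for Kpy against Kac (11), 0 to 6 for Kpy against Kla (4) and 3 to 7 for Kla against Kac (4). An estimated correlation gave 0 lists in each of the 5 comparisons with a called list, and fry gave 0 in all of them but Kpy against Kac, where it gave 8. Without both Kpy libraries numbered 1 the count was 0 for Kpy after oxamate, Kpy minus Kac and Kpy against Kla, and 6 for Kpy against Kac. For Kla: oxamate against PBS, the replicate block gave 2 lists, library quality weights 2 and members matched by position 5, and members matched by position gave 10 for Kla against Kac. The cause was not tested.

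Directions that reversed were all of values that passed no test. SIRT3 in Kpy (0.03) was -0.19 with scaling to the list of other cell types, -0.28 without both Kpy libraries numbered 1 and -0.38 to 0.72 with 1 library left out, and the window with the LDHB ID in Kpy (-0.44) was 0.27 without both and -1.40 to 0.09 with 1 left out. With 1 library left out, HAT1 in Kpy (-0.24) was -0.76 to 0.81 and LDHA in Kpy (-0.36) -0.62 to 0.02. In Kla, SIRT3 (0.15) was -0.22 to 0.45 and the LDHB ID (-0.11) -1.63 to 0.59, and in Kac the LDHB ID (0.20) was -0.25 to 0.86 and LDHA (0.29) -0.11 to 0.60. The cause was not tested. The correlation of mark levels across windows, Kla and Kac (Pearson 0.891) was 0.864 by Spearman and 0.876 in only the windows past the filter.

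The labels number the replicates but do not say that equal numbers share a culture or day. Correlations of centred values between libraries with the same number, over 15 pairs of groups, ran from -0.11 to 0.16 with a median of 0.047. The 2 above 0.1 were Kpy PBS with Kpy oxamate (0.16) and Kac PBS with Kac oxamate (0.13). With a single Kac PBS library in each comparison, windows higher than Kac in both Kpy and Kla numbered 112 and 152 (764 in the report) and lower ones 357 and 336 (1080), with fewer libraries in each. The replicate block gave 0 windows in each oxamate comparison, 4517 for Kpy against Kac, 17 for Kpy against Kla and 2612 for Kla against Kac. Other pseudocounts and quartile filters were planned only for normalized values and were not run, since the values are counts. For the oxamate effects, the fit over all 12 libraries gave a median SE of 0.382 in Kpy, 0.343 in Kla and 0.344 in Kac. These SEs rest on a spread pooled over the marks. Libraries of a group correlated at 0.715 and 0.71 in Kpy and at 0.883 to 0.927 in Kla and Kac. Simulated 2-fold changes were recovered in 20%, 18% and 13% of windows, with 53, 0 and 1 false calls.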

Other observations

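The families in this part, both tests of mitochondrial reads, the estimated correlation after the trend was removed and scaling to the list of other cell types were chosen only after the data were seen. Promoters of olfactory receptors, the odour sensors of the nasal epithelium, took a larger share of Kpy than of Kac counts. They had 17.8 ± 6.32 CPM in Kpy, 9.08 ± 0.585 in Kla and 5.16 ± 0.238 in Kac (PBS, SD, n = 2). Housekeeping promoters were 1.92 and 4.19 times these windows in the Kpy PBS libraries, and 13.8 and 12.5 times in Kac PBS. A lower signal over background in Kpy would also raise such low windows. It cannot be told apart here from a difference between marks, for these receptors, protocadherins or keratin-associated proteins. Of 294 windows 142 were higher and 0 lower in Kpy than in Kac (median log2 fold change 2.25, camera adjusted p = 1.09e-28, and adjusted p = 0.066 with an estimated correlation), and 23 were higher and 0 lower in Kla than in Kac (0.98, 5.24e-13, and 0.096 with an estimated correlation). Clustered protocadherins, cell surface proteins of neurons, had 14.5 ± 6.23 CPM in Kpy, 8.99 ± 0.181 in Kla and 3.14 ± 0.268 in Kac, with 23 of 51 higher in Kpy than in Kac (2.64, 1.66e-13, and 0.074 with an estimated correlation) and 7 higher in Kla (1.78, 7.18e-14, and 0.066). Keratin-associated proteins had 13 of 68 higher in Kpy than in Kac (1.21, 1.45e-07, and 0.22 with an estimated correlation), and C/D box small nucleolar RNAs 41 of 133 higher and 11 lower (1.47, 6.3e-05, and 0.15). The mean level of the small nucleolar RNA windows was 21.1 ± 2.49 CPM in Kpy and 21.5 ± 3.04 in Kac and did not follow that median. Against Kla, olfactory receptors had a median of 1.12 in Kpy (4.22e-22, and 0.061 with an estimated correlation), with 1 of 294 higher singly. The directions of these medians held under each scaling.

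Zinc finger genes, mostly transcription factors, were the 1 family of the 12 that passed with an estimated correlation as well, with 52 of 451 windows higher and 13 lower in Kla than in Kac (median 0.50, camera adjusted p = 1.25e-06, and adjusted p = 0.032 with an estimated correlation). Their mean levels were 30.6 CPM in Kpy, 34.6 in Kla and 32.8 in Kac (PBS, n = 2), and Kpy against Kla had a median of -0.20 (9.11e-05, and 0.061 with an estimated correlation), with 0 of 451 passing singly. Mitochondrial ribosomal proteins had 8 of 54 lower and 1 higher in Kpy than in Kac (-0.43, 0.000838, and 0.22 with an estimated correlation). Proteasome subunits had 3 of 30 lower (-0.46, 0.00475, and 0.22) and ubiquitin-conjugating enzymes 5 of 30 lower and 1 higher (-0.49, 0.0101, and 0.22). Transfer RNA synthetases (-0.26, 0.122) and solute carriers (0.07, 0.39) did not pass in Kpy against Kac. MicroRNA windows (0.36, 0.00127) and long intergenic noncoding RNA windows (0.44, 0.00127) did, each with adjusted p = 0.22 with an estimated correlation. After oxamate, olfactory receptors in Kla had a median of 0.34 (1.38e-05, and 0.7 with an estimated correlation) and keratin-associated proteins 0.54 in Kpy (0.000699, and 0.81) and 0.30 in Kla (0.00633, and 0.7), and long intergenic noncoding RNA windows 0.14 in Kla (0.0224, and 0.7), with 0 members passing. Calls at the preset correlation that ended with an estimated one were also made in Kla against Kac for keratin-associated proteins (0.84), C/D box small nucleolar RNAs (1.01), microRNA windows (0.24) and mitochondrial ribosomal proteins (-0.27). In Kpy against Kla they were made for keratin-associated proteins (0.33), clustered protocadherins (0.61), long intergenic noncoding RNA windows (0.35), proteasome subunits (-0.17) and ubiquitin-conjugating enzymes (-0.16). The directions in this paragraph held under each scaling.

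HOX and ribosomal protein promoters were lower in Kpy and in Kla than in Kac, and a technical explanation is that all strong windows are compressed alike in the library with the weaker signal, which a trend on the Kac level of the oxamate libraries would remove. After its removal HOX promoters had -0.52 ± 0.37 in Kpy against Kac (median log2, SD over members; -1.46 ± 0.57 before; adjusted p = 0.000147), and ribosomal protein promoters -0.53 ± 0.56 in Kpy (-1.12 ± 0.70 before; 9.29e-06) and -0.54 ± 0.49 in Kla (-0.99 ± 0.65 before; 2.15e-05). These 3 calls held at the preset correlation, though not with an estimated one (adjusted p = 0.69, 0.69 and 0.87). The median left exceeds its SD for HOX promoters in Kpy and ribosomal proteins in Kla, and does not for ribosomal proteins in Kpy. That SD is the spread over members and not the error of the median. The test therefore does not decide whether compression is the whole cause, and the question stays open for all 3. HOX promoters in Kla went from -1.12 ± 0.55 to -0.25 ± 0.34 (adjusted p = 0.165), a call that ended because the median shrank, so compression could account for them. A difference between the marks themselves stays open, as does one between the antibodies, which the design cannot separate from the marks.

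With the trend removed, and at the preset correlation, 3 lists passed in Kpy against Kac in PBS (11 before), 1 in Kla against Kac (4), 2 in Kpy against Kla (4) and 1 in Kpy after oxamate (7). Replication-dependent histones were among them in Kpy against Kac (-0.42 before and -0.77 after, adjusted p = 2.41e-06), in Kpy against Kla (-0.52 and -0.51, 2.39e-08) and in Kpy after oxamate (-0.42 and -0.44, 0.00256). With an estimated correlation these had adjusted p = 0.69, 0.87 and 0.85 after the trend was removed and 0.38, 0.58 and 0.64 before. Among families, the median of olfactory receptors in Kpy against Kac went from 2.25 to 0.38 (0.0322), that of clustered protocadherins from 2.64 to 0.24 (0.459), and that of zinc finger genes in Kla against Kac from 0.50 to 0.23 (0.00453). In Kpy against Kac, keratin-associated proteins went to -0.14 (0.459), C/D box small nucleolar RNAs to -0.07 (0.572), mitochondrial ribosomal proteins to -0.13 (0.128), proteasome subunits to -0.28 (0.128), ubiquitin-conjugating enzymes to -0.17 (0.344), microRNA windows to 0.12 (0.452) and long intergenic noncoding RNA windows to -0.05 (0.452), so these 7 calls ended, as did that of clustered protocadherins. In Kla against Kac, olfactory receptors went to -0.06 (0.805) and no longer passed, and clustered protocadherins to 0.37 (0.0135). In Kpy against Kla, olfactory receptors went to 0.37 (4.24e-05) and zinc finger genes to -0.29 (3.84e-09). After oxamate, olfactory receptors in Kla went to 0.11 (0.441) and keratin-associated proteins to 0.09 in Kla (0.441) and 0.34 in Kpy (0.0558), and long intergenic noncoding RNA windows to 0.05 in Kla (0.441), which ended these 4 calls. Of the further calls in Kla against Kac and Kpy against Kla, 1 was left, long intergenic noncoding RNA windows in Kpy against Kla (0.15, 0.00811). C/D box small nucleolar RNAs in Kpy against Kla (-0.14, 0.00976) and long intergenic noncoding RNA windows in Kla against Kac (-0.23, 0.00115) passed only after the trend was removed. Before removal they had adjusted p = 0.69 and 0.87 with an estimated correlation. All family values after removal are at the preset correlation. The trend is built on the Kac oxamate libraries, so effects of oxamate in Kac, and differences from them, are not given after its removal.

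Windows higher in Kpy than in Kla held copies of mitochondrial DNA in 3 of 16 cases, and a candidate explanation is reads of mitochondrial DNA placed on nuclear copies. In Kpy oxamate replicate 1 the windows on chromosome 1 were at 0.19 and that on chromosome 17 at 0.3 of the mean of the other Kpy libraries, but the library stood out by these same windows, and the 10 other windows with such copies were at 0.73, so the test decides nothing for the 3. For the other 13 windows the median ratio was 0.82 (0.3 to 1.1, with OR9I1 and LOC101928516 under 0.5), which decides nothing either, since none of the 13 holds such a copy and the 10 other windows that do were at 0.73. These 13 include the serotonin receptor gene HTR1E, the phospholipase D family gene PLD5, NTM and LRRN1. No biological explanation was tested, and a difference between Kpy and Kla stays open for all 16.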
